A study of Mus musculus with 20 samples.

How the data were processed

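Total RNA of the mouse ileal mucosa was profiled by real-time PCR on the TaqMan OpenArray mouse inflammation panel in 20 samples, 5 in each of 4 groups. Per the labels' protocols, RNA was isolated with the mirVana kit, its integrity was checked on a Bioanalyzer, and the cDNA was cycled on OpenArray plates. Groups were taken from the labels for intrarectal and oral treatment. For Nissle 3, 4 and 5 the label of the experimental group names the healthy controls, while the title, the description and both treatment labels name the Nissle group. These 3 samples were kept in the Nissle group, and the counts of called assays, the named assays, the list tests and the opposition were also computed without them.

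The deposited table holds raw cycle threshold (Ct) values, not normalized, per the file headers: the number of PCR cycles needed to reach a fixed fluorescence, so that a lower value means more template. It has 648 assays for 584 gene symbols, 50 of them with more than 1 assay. A value of 40 stood for an assay without amplification and filled 1273 of 12960 cells (9.82%), and 1 further cell was empty. Whether a value averages several wells, and which baseline and threshold settings were used, is not given in the sources used here. Symbols were updated through a RefSeq gene table for GRCm38.p6, used for names alone: 21 symbols were renamed and 1 did not match. Coordinates were not used here. No replicate pair held identical values, and the SD of the differences between samples of a group was 0.607 to 1.97 cycles.

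Depth is given here as the number of assays with a value, 570 to 594 per sample, and as the mean Ct of the 544 assays with a value in every sample, 22.6 to 24.3 cycles. The relative level of an assay was the negative of its Ct minus that mean in the same sample. It is a log2 value if each cycle doubles the product, which was assumed and not measured. Undetermined values were left missing.

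Levels were compared with limma 3.58.1 in R 4.3.3: linear fits of the 4 group means over all 20 samples, empirical Bayes moderation with a trend in the mean level, two-sided tests, and Benjamini-Hochberg adjustment at 0.05 within each comparison. The 569 assays (512 genes) with at least 3 values in each group were tested, and the median SE of a log2 difference was 0.42. Gene lists were fixed by name beforehand and tested with limma's camera (preset correlation between genes 0.01) on 1 assay per gene, the one with the lowest mean Ct. The 22 lists with at least 5 measured members were tested and adjusted together. They are named here only where they are described: neutrophil markers, pro-inflammatory cytokines, chemokines, leukocyte adhesion molecules and integrins, macrophage, monocyte and dendritic cell markers, chemokine and chemoattractant receptors, MAP kinase and PI3 kinase signalling, the TNF superfamily, inflammasome and cell death genes, and the interferon response with STAT signalling. For called lists, the number of members passing when adjusted over the list alone was counted, the correlation was also estimated from the data, and fry was run. Median, mean and test direction differed in sign in 37 of 132 list tests, none of them called (smallest adjusted p = 0.726).

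Detection was compared with Fisher's exact test per assay. Opposition was the covariance across assays of the change with DNBS and the change with an oral treatment, each computed with different DNBS samples, and was tested with 10000 permutations of the sample labels. The groups, the lists, the tests with limma, camera and Fisher's exact test, the opposition test, and all alternatives but the 6 added later were chosen before the data were examined. The exact permutation tests of sample averages, the tests on Atrn and on single-exon assays, and the counts of splits by shared number and after centring sections were chosen after results were seen. The named genes follow a rule fixed at the same time: per comparison, the assays past the threshold (up to 12 in each direction), with fewer than 12 also the 8 assays with the smallest unadjusted p as values that did not pass, up to 4 members of each described list with the smallest p, the usual readouts Il1b, Il6, Tnf, Il10, Il17a, Ifng, Il12b, Nos2 and Ptgs2, and assays called in detection. Genes outside it are marked as chosen after their values were seen.

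The titles number the samples, and groups share numbers. The labels do not say that a number marks a shared litter, batch or day, so the main model has no block. In the DNBS and healthy groups, which share 3 numbers, same-numbered samples deviated together (correlations of 0.14 to 0.49 between their deviations from the group means), and 2 of these 3 correlated best with their own number. This pairing comes from the data and not from the labels, and values with the number as a block are given beside that comparison.

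The fits and the opposition test were tested on simulated data. With changes added to 200 of the 569 assays between the DNBS and healthy groups, limma recovered 42% of the changes of log2 1, 94% of 2, 92% of 3 and 100% of 4, with 7 false calls. It made 0 calls in each of the 6 comparisons when no change was added. The simulated assays were independent of each other, and so many changed assays ease the adjusted threshold. Recovery with few changed assays was not tested. Neither rate carries over to the real data, where random splits of the samples gave up to 34 calls. Fisher's exact test can call no assay here with fewer than 15 or 16 full separations, so its power for fewer was not tested. For opposition of CEC and DNBS, a full simulated opposition with a true covariance of -0.25 gave -0.22 (permutation p = 0.0030), and no opposition gave -0.0043 (permutation p = 0.862). With independent assays this overstates the power in the real data, where a covariance of -0.23 for CEC gave a permutation p of 0.0691.

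Alternatives were other scalings (20 reference assays, the median, quantile normalization, none), other filters on missing or late values, missing values set to the highest Ct plus 1, other variance models, fits to the groups compared alone, sample weights, the number as a block, and leaving out each sample or the 3 Nissle samples. After the data were seen, 6 were added: the block in the list tests, leaving out the 3 Nissle samples in the list tests, centring each run of 54 assays within a sample (called a section), leaving out the 53 single-exon assays, leaving out the 3 samples with the widest section shifts, and removing values under cycle 10.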

Results

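Transcripts of inflammation-related genes were measured in ileal mucosa by real-time PCR with 648 assays in 20 mouse samples. The 4 groups held 5 samples each. Healthy controls received phosphate-buffered saline (PBS) both intrarectally and by mouth. The other 3 groups received intrarectal DNBS (dinitrobenzene sulfonic acid, a hapten that causes colitis when given this way), together with oral PBS (DNBS group), an oral treatment known from the labels as CEC (CEC group) or oral Nissle (Nissle group; the name is that of a probiotic Escherichia coli strain). Between 570 and 594 assays gave a value in a sample. The mean cycle threshold (Ct) of the assays measured in every sample lay between 22.6 and 24.3 cycles. No sample gave a value for 26 assays, among them those for Tnf and Il10. The series description speaks of RNA pooled from mice and leaves open whether a sample is 1 mouse, so p-values measure only the spread between these samples, which may be technical. Relative levels are log2 values with the sample mean at 0, and all tests were two-sided.

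What DNBS did to the ileum was read from the DNBS group against the healthy controls. Atrn, which encodes attractin, a glycoprotein with roles in immune cell interactions and pigmentation, fell in the DNBS group by 3.04 on the log2 scale (SE 0.45), which made it 8.25-fold lower. Its relative level was 2.71 ± 1.01 in the healthy controls and -0.34 ± 0.60 in the DNBS group (SD, n = 5 each), and all 5 DNBS samples lay below the lowest healthy sample. The assay was Atrn_Mm00437746_m1. In raw cycles the healthy samples lay between 19.6 and 22.4 and the 15 samples of the 3 DNBS-treated groups between 21.9 and 24.9. Atrn was the only assay called among 569 (limma, adjusted p = 0.000628), while 83 assays had an unadjusted p under 0.05. With no true difference 28.45 of 569 would be expected in any comparison, and random splits of these samples gave up to 139.

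**Figure D1:**
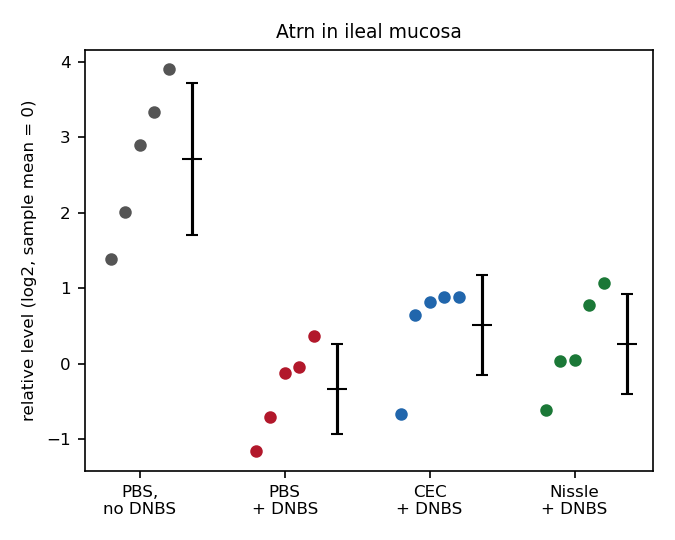
Relative level of Atrn (y axis, log2, sample mean at 0) in each of the 20 samples by group (x axis), with group means and SD as bars. The healthy samples sit between 1.39 and 3.91, and the 15 samples given DNBS between -1.16 and 1.07.

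The 8 assays with the next smallest p-values of that comparison did not pass the threshold (adjusted p = 0.122 for each). Il6, an acute-phase cytokine, was 24.6-fold higher in the DNBS group with assay Il6_Mm00446190_m1 (log2 4.62, SE 1.22), at -1.72 ± 0.79 against -6.33 ± 0.76 in the healthy controls (SD, n = 5 each). Cxcl2, a neutrophil chemokine, was 27.4-fold higher (log2 4.78, SE 1.28). In both genes all 5 DNBS samples lay above the highest healthy sample. Socs2, a suppressor of cytokine signalling, had a log2 difference of -0.95 (SE 0.24), Sectm1b -1.94, and the kinase gene Akt1 0.63. Scn9a (-1.75), Ccr1l1 (-2.06) and the eotaxin receptor gene Ccr3 (-1.70) were measured with single-exon assays, a class that can also amplify genomic DNA and whose 53 tested members had a median of -0.65. The exon-junction assay of Ccr3 gave -0.26 (SE 0.88). Chi3l3, a chitinase-like protein of macrophages named here after its values were seen, was 86.6-fold higher (log2 6.44, SE 1.89). Among the other usual readouts, the log2 differences were 1.71 and 1.81 for the Il1b assays, 0.49 for Il17a, 0.78 for Nos2, 1.08 for Ptgs2, 0.70 and 0.63 for Ifng, and 0.25 and -0.47 for Il12b. The second Il6 assay, Il6_Mm01210733_m1, gave -4.06 with an SE of 3.75, and in the healthy controls it had only 3 values, 1 of them a Ct of 5.74 in healthy 5.

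As a group, the neutrophil markers rose in the DNBS group: all 7 measured members were higher, with a median of 1.83 on the log2 scale (camera, adjusted p = 0.0217). This call did not hold with an estimated correlation (adjusted p = 0.848 with an estimated correlation). The calprotectin genes S100a8 and S100a9 had log2 differences of 3.83 (SE 1.40) and 3.96 (SE 1.45), lactoferrin (Ltf) 1.83 (SE 0.57), and the neutrophil chemokine receptor gene Il8rb 2.45 (SE 1.19), whereas the remaining members Ncf1, Camp and Fpr1, named after their values were seen, differed by 0.19, 0.14 and 0.09. No member passed over all assays, and 3 passed when adjusted over the list alone. Averaged per sample, the markers stood at 0.77 ± 1.04 in the DNBS group and -1.02 ± 0.52 in the healthy controls, with 4 of 5 DNBS samples above the highest healthy one and DNBS 5 at -0.96. An exact permutation test of these averages, added after they were seen, gave p = 0.0238 (0.143 adjusted over 6 comparisons). Pro-inflammatory cytokines did not pass as a list, with 15 of 19 members higher, a median of 0.49 and an adjusted p of 0.0609 (adjusted p = 0.848 with an estimated correlation). This list holds Il6_Mm01210733_m1 and not the other Il6 assay. It was called higher with values under cycle 10 removed (adjusted p = 0.0113), with reference assays (0.0320), without the 3 samples of widest section shifts (0.0483), and without any of DNBS 3, Nissle 1 or healthy 1b, 3, 5 or 6 (0.00956 to 0.0475).

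With the sample number as a block, 2 assays were called in this comparison, Atrn and Il18 (log2 1.71, SE 0.30, adjusted p = 0.0210), which is named after its values were seen, and the neutrophil list was not (adjusted p = 0.0815). Healthy 1b and healthy 6 add nothing to this fit, since each has a number of its own. Without normalization Atrn did not pass (log2 -2.81, adjusted p = 0.109), whereas a fit to both groups alone called 9 assays, among them Il6_Mm00446190_m1 (adjusted p = 0.000468), Cxcl2 (adjusted p = 0.00332), Socs2 and Sectm1b. The count rose to 101 with array weights (49 higher, 52 lower, 22 of them single-exon), to 7 without DNBS 5 and to 6 without Nissle 1. The neutrophil call was lost without DNBS 2 (adjusted p = 0.133), healthy 4 (0.0849) or healthy 5 (0.0519).

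**Figure D2:**
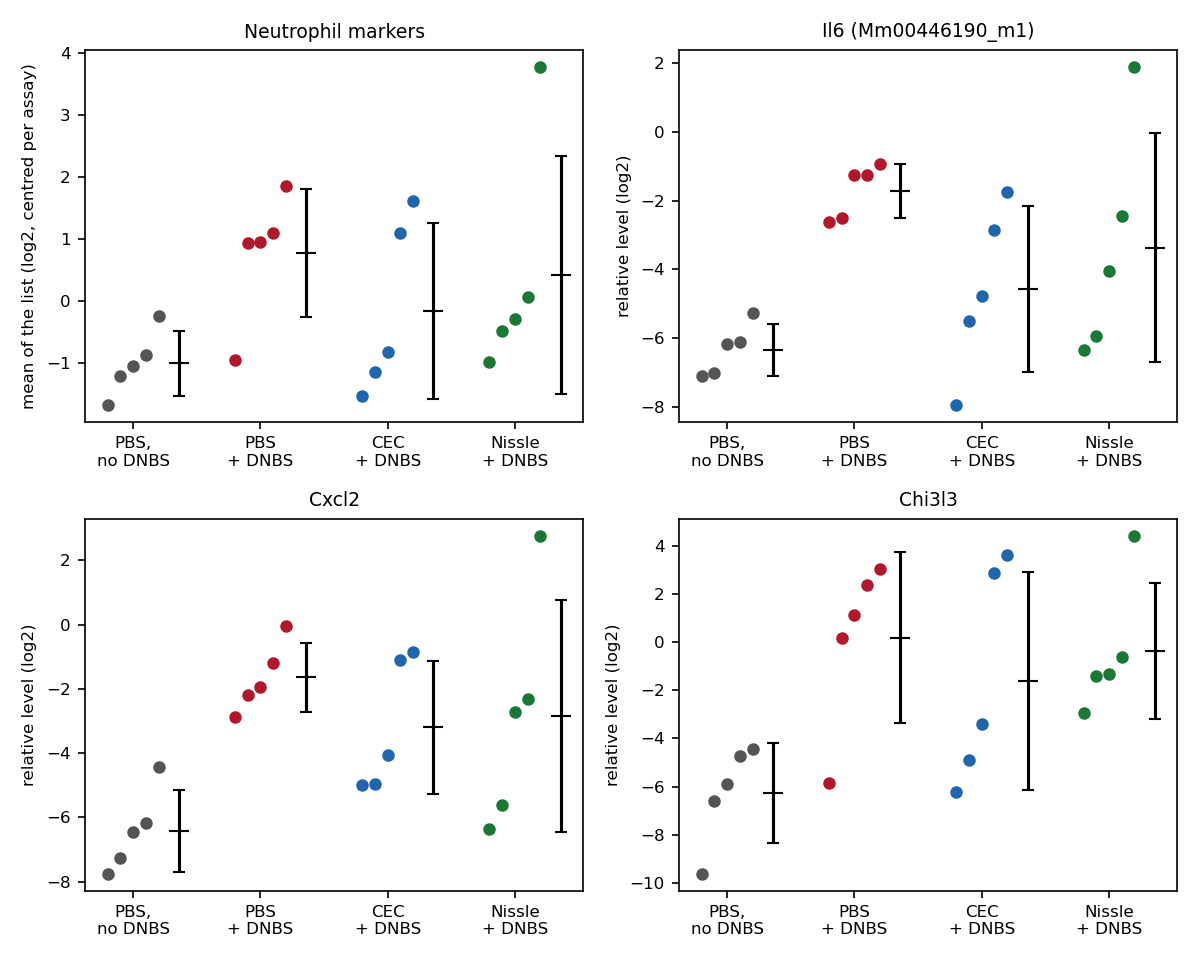
Mean relative level of the neutrophil markers, and relative levels of Il6 (assay Il6_Mm00446190_m1), Cxcl2 and Chi3l3 (y axes, log2), in each sample by group (x axis), with group means and SD as bars. Nissle 1 has the highest value of all samples in each panel, and its neutrophil mean is 3.77.

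The CEC group was compared with the healthy controls to show how far DNBS-treated mice given CEC differed from untreated mucosa. Atrn fell by 2.20 on the log2 scale (SE 0.45) and was 4.59-fold lower than in the healthy controls (0.51 ± 0.66 in the CEC group, SD, n = 5), with all 5 CEC samples below the lowest healthy sample. It was the only call among 569 assays (limma, adjusted p = 0.0445). An unadjusted p under 0.05 was found for 22 assays, fewer than the 28.45 expected with no true difference. Macrophage, monocyte and dendritic cell markers rose as a list, with 8 of 11 members higher and a median of 0.53 (camera, adjusted p = 0.0257; adjusted p = 0.544 with an estimated correlation). Its members with the smallest p were the chemokine receptor gene Cx3cr1 (log2 0.95, a single-exon assay), the costimulatory ligand gene Cd86 (1.26), the integrin gene Itgam (0.82) and the Fc receptor gene Fcgr2b (1.37). Leukocyte adhesion molecules and integrins rose as well, with 4 of 5 members higher and a median of 0.68 (camera, adjusted p = 0.0339; adjusted p = 0.544 with an estimated correlation), among them P-selectin (Selp, 1.07), Itgal (0.68) and Itgb2 (0.48). Itgam belongs to both lists, and 0 members of either passed with limma over all assays or when adjusted over the list alone, while 2 macrophage and 0 adhesion members had an unadjusted p under 0.05.

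None of the remaining assays passed in that comparison (adjusted p = 0.803 for those named next). Chi3l3 was 25.1-fold (log2 4.65, SE 1.89) and Cxcl2 9.34-fold higher in the CEC group (log2 3.22, SE 1.28). The reference gene Hprt1 differed by 0.95 (SE 0.33), the phospholipase gene Pla2g4c by -2.37, lymphotoxin beta (Ltb) by -0.81, Lif by -0.87 and the interferon-induced chemokine Cxcl9 by -1.0. Il6_Mm00446190_m1 had a log2 difference of 1.77, the Il1b assays 0.96 and -0.17, Il17a -0.12, Nos2 0.72, Ptgs2 0.17, Ifng 1.35 and 0.18, and Il12b 0.93 and -0.16. Neutrophil markers had a median of 0.66 with 6 of 7 higher (adjusted p = 0.261), and the averages per sample did not differ beyond the spread (0.85, exact permutation p = 0.286). Pro-inflammatory cytokines had a median of 0.23 and a mean of -0.11 (adjusted p = 0.864), the mean lying below 0 with Il6_Mm01210733_m1 at -6.99.

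The Atrn call of the CEC group was lost in 14 of 20 fits that left out 1 sample: without any of the 5 CEC samples (adjusted p from 0.0746 to 0.212), without DNBS 3, 4 or 5 (0.0560 to 0.0653), without Nissle 1, 2 or 3 (0.0547 to 0.0666), and without healthy 1b, 3 or 4 (0.154 to 0.213), with log2 changes of -2.53 to -1.90 over all 20. It was also lost under other settings, among them quantile normalization (adjusted p = 0.133), no normalization (0.990) and a fit to both groups alone (0.201), with adjusted p-values from 7.64e-07 to 0.990 over all settings. The macrophage call was lost without CEC 1 (adjusted p = 0.170), CEC 3 (0.122), healthy 1b (0.0843) or healthy 4 (0.0554), and the adhesion call without the same 4 samples (0.0554 to 0.227) or healthy 5 (0.0511). Both ended without single-exon assays (0.0777 and 0.0664), and the adhesion call also with reference assays (0.0571) and without the 3 samples of widest section shifts (0.0519).

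Against the same healthy controls, the Nissle group also had lower Atrn, which fell by 2.45 on the log2 scale (SE 0.45) and was 5.45-fold lower (0.26 ± 0.67 in the Nissle group, SD, n = 5). All 5 Nissle samples lay below the lowest healthy sample. Atrn was again the only assay called of 569 (limma, adjusted p = 0.0122), and 54 had an unadjusted p under 0.05. The 3 comparisons with the healthy controls share the same 5 healthy samples and are not independent of each other. Of the 22 lists, 4 rose in the Nissle group: neutrophil markers (7 of 7 higher, median 1.16, camera adjusted p = 0.0226), macrophage, monocyte and dendritic cell markers (11 of 11, median 0.23, mean 0.55, adjusted p = 0.0226), adhesion molecules and integrins (4 of 5, median 0.46, adjusted p = 0.0442) and pro-inflammatory cytokines (15 of 19, median 0.49, adjusted p = 0.0442). None of these calls held with an estimated correlation (adjusted p = 0.594 with an estimated correlation for each). Chemokines had a median of 0.13 with 18 of 28 higher (adjusted p = 0.0504), and were called after centring sections (0.0478), without the 3 Nissle samples of contradictory label (0.00425) and without any of CEC 3, 5 or 8, DNBS 1, 2 or 4, Nissle 2, 4 or 5, or healthy 5 or 6 (0.00725 to 0.0499), though not with an estimated correlation (0.594). No list member passed over all assays (limma, 2 neutrophil, 0 macrophage, 1 adhesion and 1 cytokine member with an unadjusted p under 0.05), and 1, Selp, passed when adjusted over the list alone.

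Nissle 1 stood apart in these lists: its mean over the neutrophil markers was 3.77, while the nearest Nissle sample stood at 0.0619. In this comparison S100a9 had a log2 difference of 3.17 (SE 1.45), S100a8 3.05 (SE 1.40), the cathelicidin gene Camp 1.60 (SE 0.83) and Ltf 0.76. Of the macrophage markers, Fcgr2b differed by 1.53, Cd86 by 1.12, the scavenger receptor gene Cd163 by 0.97 and the endotoxin co-receptor gene Cd14 by 0.85. Selp was 4.07-fold higher (log2 2.02, SE 0.59, adjusted p = 0.458), Itgal differed by 0.68, Itgb2 by 0.46 and Itgam by 0.13. Among the cytokines Il17a had a log2 difference of 1.70, Il1f9 2.58 and Ltb -0.76, and Il6_Mm01210733_m1, which rests on the early value of healthy 5, -6.39. Il6_Mm00446190_m1 differed by 2.96, the Il1b assays by 1.78 and 1.2, Nos2 by 0.59, Ptgs2 by 0.46, Ifng by 1.34 and 0.64, and Il12b by 1.10 and 0.19. Socs2 (-0.88), Chi3l3 (5.88, SE 1.89, 58.9-fold), Tlr3, a sensor of double-stranded RNA (-1.14), the complement receptor gene Cr2 (-1.91), Cxcl2 (3.57), Kit (-0.73) and Map2k6 (-0.94) did not pass (adjusted p from 0.395 to 0.488).

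Without Nissle 1 all 4 list calls ended (adjusted p = 0.488 for neutrophil markers, 0.171 for macrophage markers, 0.412 for adhesion molecules and 0.881 for cytokines), and without healthy 4 they ended as well (0.0770 to 0.164). The adhesion call was also lost without Nissle 2 (adjusted p = 0.0817), healthy 1b (0.115) or healthy 5 (0.0816), the cytokine call without CEC 1, CEC 7, Nissle 3, Nissle 4 or healthy 3 (0.0560 to 0.0839), and the Atrn call without Nissle 3, Nissle 4, healthy 3 or healthy 4 (0.0504 to 0.0649). The adhesion call ended after centring sections (0.0799) and without the 3 samples of widest section shifts (0.0815), the cytokine call with reference assays (0.0799), and both without single-exon assays (0.0599 and 0.0671). Leaving out the 3 Nissle samples of contradictory label (0.0849), a fit to both groups alone (0.0911) and no normalization (0.501) ended the Atrn call as well, with adjusted p-values from 1.27e-07 to 0.501 over all settings.

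The effect of oral CEC in DNBS-treated mice was read from the CEC group against the DNBS group. All 7 neutrophil markers had lower mean values in the CEC group, with a median of -1.18 on the log2 scale, and 16 of 19 pro-inflammatory cytokines were lower, with a median of -0.61. Neither list passed (camera, adjusted p = 0.333 and 0.166; adjusted p = 0.705 with an estimated correlation for both). Il1b differed by -1.98 with assay Il1b_Mm99999061_mH (SE 0.80, adjusted p = 0.416), the gp130 cytokines Lif and Osm by -1.01 and -1.49, Il18 by -0.65, and Il6_Mm00446190_m1 by -2.85 (SE 1.22, adjusted p = 0.444). Neutrophil members with the smallest p were Ltf (-1.18), Ncf1 (-0.42), S100a8 (-1.89) and S100a9 (-1.66), and the averages per sample differed by -0.93 (exact permutation p = 0.310). Of the single assays, 0 of 569 were called by limma (smallest adjusted p = 0.367), and 61 had an unadjusted p under 0.05. Those with the smallest p were transglutaminase 2 (Tgm2, log2 -0.84, SE 0.21), Akt1 (-0.59, SE 0.18), the apolipoprotein gene Apoa1 (1.59), the histone deacetylase gene Hdac5 (1.17) and the hypoxia factor gene Hif1a (-1.04), together with Cx3cr1 (1.28), Ifne (1.93) and the gut-homing receptor gene Ccr9 (1.59), which have single-exon assays. The median of all single-exon assays in this comparison was 0.64. The other readouts differed by -0.75 (Il1b_Mm01336189_m1), -0.61 (Il17a), -0.07 (Nos2), -0.91 (Ptgs2), 0.65 and -0.45 (Ifng), and 0.67 and 0.30 (Il12b).

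Both lists were called lower in the CEC than in the DNBS group without CEC 3 (adjusted p = 0.0118 for cytokines and 0.0345 for neutrophil markers) and without DNBS 5 (0.0391 for each), and the cytokine list also after centring the sections of the plates (0.0313), while with an estimated correlation, over all samples, the adjusted p was 0.705 for both. With array weights limma called 47 assays, 25 higher and 22 lower, 9 of them single-exon. For this count chance could not be excluded: 12 of 100 random splits of the samples, the real one included, gave as many calls (highest other 100).

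Oral Nissle was compared with oral PBS in DNBS-treated mice in the same way, and 0 of 569 assays were called by limma (smallest adjusted p = 0.850, 24 with an unadjusted p under 0.05). Annexin A1 (Anxa1), a mediator that limits inflammation, had a log2 difference of -0.87 (SE 0.30), the eotaxin Ccl24 -1.53 (SE 0.57), hepatocyte growth factor (Hgf) -0.83, Lrp8 -1.02, Glmn -0.75, Akt1 -0.51, Tgm2 -0.59 and the reference gene Tbp -0.77. Il6_Mm00446190_m1 differed by -1.66, Il17a by 1.21, the Il1b assays by 0.06 and -0.61, Nos2 by -0.19, Ptgs2 by -0.62, Ifng by 0.64 and 0.01, and Il12b by 0.85 and 0.66. The lists with the smallest p were chemokine and chemoattractant receptors, with 14 of 21 members higher and a median of 0.16, and MAP kinase and PI3 kinase signalling, with 8 of 10 lower and a median of -0.25 (camera, adjusted p = 0.733 for both). Ccr9 (1.26), Ccr3 (1.18, against 0.28 with its exon-junction assay), Ccr6 (1.05) and Cxcr6 (0.85) of the receptor list were single-exon assays, and the kinase list held Mapk14 (-0.46), Map2k6 (-0.34) and Mapk8 (0.51). Neutrophil markers had a median of -0.79 with 5 of 7 lower (adjusted p = 0.871) and included Nissle 1, the sample with the highest neutrophil mean. Pro-inflammatory cytokines and neutrophil markers were each called lower in the Nissle group without Nissle 1 (adjusted p = 0.0224 for both), while with an estimated correlation, over all samples, no list passed (smallest adjusted p = 0.901). Without the 3 Nissle samples of contradictory label the log2 differences of Il6_Mm00446190_m1 (0.63), Il1b_Mm99999061_mH (1.28), Ptgs2 (0.34) and Nos2 (0.15) lay above 0, and chemokines, chemoattractant receptors and adhesion molecules were called higher as lists (adjusted p = 0.0308 for each), with Nissle 1 as 1 of 2 Nissle samples left.

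Both oral treatments were set against each other in the CEC and Nissle groups. Chemokines fell as a list in the CEC group relative to the Nissle group, with 19 of 28 members lower and a median of -0.37 (camera, adjusted p = 0.0012; adjusted p = 0.288 with an estimated correlation). Ccl4, a chemokine for T cells and monocytes, had a log2 difference of -1.63 (SE 0.53), and the interferon-induced chemokines Cxcl9, Cxcl10 and Cxcl11 differed by -0.93, -1.08 and -1.67. Pro-inflammatory cytokines were lower in 15 of 19 members, with a median of -0.36 (adjusted p = 0.0111; adjusted p = 0.340 with an estimated correlation), among them Il17a (-1.82), Lif (-0.76), Il1b_Mm99999061_mH (-1.37) and Il27 (-1.0). In the TNF superfamily 16 of 25 members were lower, with a median of -0.19 (adjusted p = 0.0348; adjusted p = 0.324 with an estimated correlation), among them Tnfsf11 (-1.02), Tnfrsf1b (-0.60), Tnfsf9 (-1.03) and Tnfrsf9 (-0.76). No single assay was called by limma (0 of 569, smallest adjusted p = 0.998, 8 with an unadjusted p under 0.05), and no list member passed when adjusted over the list alone. The remaining assays with the smallest p were Bmp1 (0.99), the acute-phase gene Orm1 (2.19), the lipoxygenase gene Alox5 (0.88), Glmn (0.58) and Socs2 (0.50), and Il6_Mm00446190_m1 differed by -1.19.

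Nissle 1 carried much of this contrast: without it none of the 3 lists passed (adjusted p = 0.456 for chemokines, 0.976 for cytokines and 0.127 for the TNF superfamily). The cytokine call was also lost without CEC 1, CEC 7 or CEC 8 (0.0545 to 0.0723), and the TNF superfamily call without CEC 1, CEC 7, Nissle 4 or Nissle 5 (0.0770 to 0.344). Centring sections ended the TNF superfamily call (0.0585), as did leaving out single-exon assays (0.0792), and reference assays ended both the cytokine and the TNF superfamily calls (0.0757 for each). Neutrophil markers, which did not pass here (6 of 7 lower, median -0.25, adjusted p = 0.118), were called lower without CEC 1, CEC 3, Nissle 3, Nissle 4 or Nissle 5 (0.00843 to 0.0359), but with all samples and an estimated correlation the adjusted p was 0.909. Without the 3 Nissle samples of contradictory label the TNF superfamily did not pass (0.623), and neutrophil markers (0.000298) and adhesion molecules (0.0497) were called lower, with Nissle 1 as 1 of 2 Nissle samples left. With all samples and an estimated correlation no list passed (camera, smallest adjusted p = 0.288).

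Whether the oral treatments moved genes against the change with DNBS was tested across the 569 assays with separate DNBS samples in both terms. The covariance of the change with CEC and the change with DNBS was -0.23 (permutation p = 0.0691), and that of the change with Nissle and the change with DNBS was -0.07 (permutation p = 0.578). The changes with CEC and with Nissle had a covariance of 0.09 (permutation p = 0.436). For CEC the covariance passed without CEC 1 (-0.29, permutation p = 0.0328), CEC 3 (-0.35, p = 0.0121 by permutation), DNBS 5 (-0.41, p = 0.0129 by permutation) or healthy 5 (-0.31, p = 0.0306 by permutation), was nearest to 0 without DNBS 4 (-0.12, permutation p = 0.395) and CEC 5 (-0.15, p = 0.208 by permutation), and was -0.19 without single-exon assays (permutation p = 0.116). The CEC covariance also passed after centring sections (-0.27, permutation p = 0.0323) and without the 3 samples of widest section shifts (-0.48, p = 0.0238 by permutation). For Nissle the covariance passed without Nissle 1 (-0.27, permutation p = 0.0189). It turned to 0.26 without the 3 Nissle samples of contradictory label (p = 0.174 by permutation).

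Some assays gave a value in some samples only, and detection was compared for 89 to 97 assays per pair of groups. Named after their values were seen, 3 assays separated groups fully. Fgf23, a hormone of phosphate balance, was detected in 5 of 5 DNBS samples, 0 of 5 healthy samples, and 1 of 5 samples in each of the CEC and Nissle groups. Scgb3a1, a secretoglobin, was detected in 0 of 5 healthy, 5 of 5 CEC, 5 of 5 Nissle and 3 of 5 DNBS samples, and the elastase assay Ela2 in 0 of 5 healthy, 5 of 5 Nissle, 2 of 5 DNBS and 1 of 5 CEC samples. Such a separation of 5 samples from 5 has an exact p of 0.00794, the smallest Fisher's test allows here, and 0 assays passed after adjustment in any comparison (1 to 3 with an unadjusted p under 0.05). At least 15 assays with a full separation would have been needed for any call.

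The plates showed a technical structure that was widest in 3 samples. In deposited order, runs of 54 assays shifted together. The shifts of the 12 runs spanned 2.87 cycles in healthy 5, 2.46 in DNBS 5 and 1.72 in DNBS 1. In the other samples they spanned 0.264 (DNBS 4) to 1.53 cycles (CEC 1). Some shifted the opposite way, such as CEC 1 in section 1 (-1.06, against 1.97 in healthy 5). Leaving out the 3 samples with the widest shifts therefore does not remove all shifts. After centring these sections, Atrn stayed lower in all 3 comparisons with the healthy controls (limma, adjusted p = 4.68e-07 for the DNBS, 7.64e-07 for the CEC and 1.27e-07 for the Nissle group). In the DNBS group Cxcl2 then passed as higher and Scn9a, a single-exon assay, as lower (adjusted p = 0.0435 for each).

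**Figure D3:**
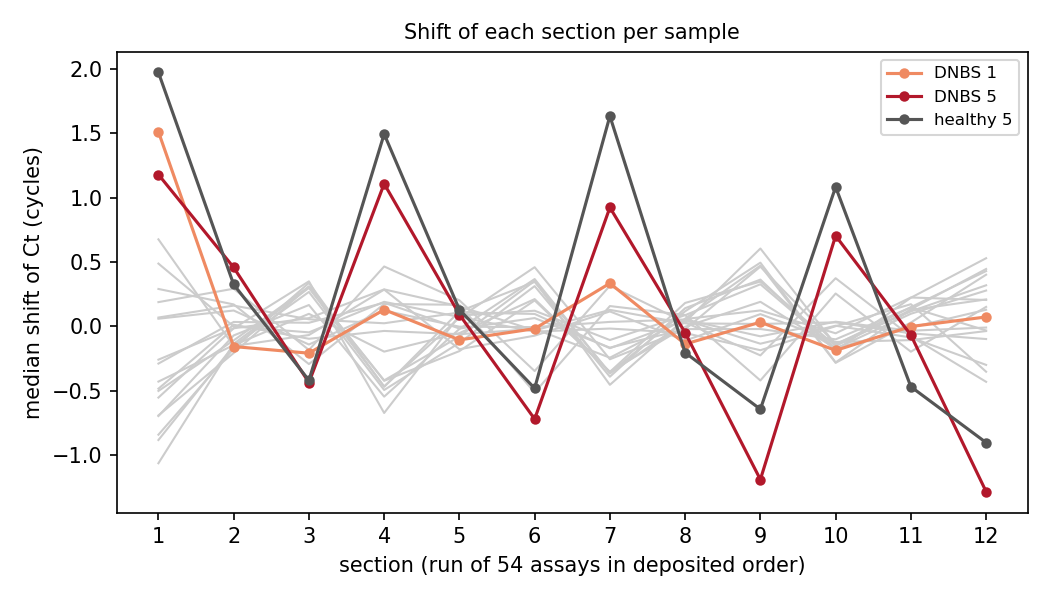
Median shift of Ct (y axis, cycles) of each of 12 sections of 54 assays (x axis) in every sample. Grey lines are the 17 other samples, and the 3 coloured samples have the widest ranges, 2.87 cycles in healthy 5, 2.46 in DNBS 5 and 1.72 in DNBS 1.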

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

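The tests on Atrn and on single-exon assays were chosen only after those results were seen. In 29 of 320 sets of values, each a sample measure or a named assay within 1 group, the highest or lowest sample stood far from the nearest other one relative to the range of the group. Chance alone gives this in about 1 in 20 such sets, and the sets share samples and genes. Nissle 1 stood above the other Nissle samples in the mean of the neutrophil markers (3.77, nearest sample 0.0619), S100a8 (6.48, nearest 0.87), S100a9 (5.48, nearest -0.68), Il1b_Mm99999061_mH (3.77, nearest -0.72), Ifng_Mm01168134_m1 (-1.90, nearest -3.86), Ptgs2 (-0.72, nearest -3.35), Camp (-1.06, nearest -4.41) and Cd14 (3.13, nearest 0.25), and below them in Sectm1b (2.16, nearest 4.11) and Ccr1l1 (-3.18, nearest -1.88). Healthy 5 had the widest shifts between sections among the healthy samples (2.87 cycles, nearest 1.04) and stood below the others in Ifng_Mm01168134_m1 (-7.71, nearest -4.64), Ifng_Mm99999071_m1 (-3.79, nearest -2.18), Cx3cr1 (-2.87, nearest -1.18), Itgal (-2.42, nearest -0.56) and Hdac5 (-2.0, nearest -1.27), and above them in Tlr3 (3.05, nearest 1.84). CEC 1 stood below the other CEC samples in Il12b_Mm00434174_m1 (-7.31, nearest -4.72), Cr2 (-6.33, nearest -2.92) and Ccl4 (-4.02, nearest -2.51), and above them in Tnfrsf1b (1.82, nearest 1.46). CEC 7 stood below them in Atrn (-0.66, nearest 0.64) and Hif1a (1.45, nearest 2.24). DNBS 5 stood below the other DNBS samples in Hprt1 (2.12, nearest 3.33) and Tgm2 (4.56, nearest 5.08). Healthy 1b stood below the other healthy samples in Il12b_Mm00434174_m1 (-7.18, nearest -4.43) and Ptgs2 (-4.60, nearest -3.35), healthy 4 below them in Camp (-7.24, nearest -5.47), and healthy 6 above them in Cr2 (-1.12, nearest -2.15).

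Atrn lay lower in each DNBS-treated group than in the healthy controls, with a gap of 0.32 on the log2 scale between the lowest healthy sample and the highest of the 15 DNBS-treated ones. Shifts between sections of the plates were argued against as the whole cause, because Atrn stayed lower after centring them in all 3 comparisons (limma, largest adjusted p = 7.64e-07, that of the CEC group, which reached 0.990 without normalization) and the gap grew to 1.77. A loss of input RNA in the DNBS-treated samples was argued against too: it needed a mean Ct at least 1 cycle above that of the healthy samples, and the difference was -0.24 cycles. What stays open is a response to DNBS, and in its place a difference between mouse cohorts or a sequence variant under the assay. These cannot be told apart, since the healthy group held the only mice without DNBS.

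Single-exon assays, which can also amplify genomic DNA, were lower in the DNBS than in the healthy group in 47 of 53 cases (median log2 -0.65, against -0.014 for the 458 assays with an m1 suffix), and an exact permutation test of their medians per sample gave a difference of -0.72 (p = 0.0159, 0.0952 adjusted over 6 comparisons, and 0.0476 after centring sections). Shifts between sections were argued against, as the median was -0.68 after centring. Genomic DNA carried in the RNA, less of it in the DNBS samples, may explain the difference and stays open. In the 7 genes with both kinds of assay, after centring sections, the single-exon change lay lower than the exon-junction change in 5, by a median of -0.16. This median lies above the bound of -0.3 that genomic DNA needed. The differences ran from -1.68 to 0.30 (SE of their mean 0.26), so these 7 genes cannot decide. The 36 assays with a mean Ct over 24 had a median of -0.93 and the other 17 one of -0.13, and an effect of DNBS on these genes themselves was not tested and stays open as well.

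Within a sample, runs of 54 assays shifted together, most in healthy 5, DNBS 5 and DNBS 1. Different mixes of genes in the sections were argued against: the SD of the difference between 2 assays of the same gene in different sections was 1.94 times as large in these 3 samples as in the other 17, and 0.957 times after centring. Unequal loading or amplification of sections is a candidate explanation, since centring lowered the SD of the same-gene differences by 12.2% (0.694 to 0.610), the measure stated beforehand. A scaled median absolute deviation, computed first, went the other way (0.439 to 0.471), so the measures disagreed: the SD dropped in the 3 samples with wide shifts (1.12 to 0.587) and not in the rest (0.575 to 0.614). No biological explanation was tested.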

How the results depend on the processing

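The fits after centring sections, without single-exon assays, without the 3 samples of widest section shifts and without values under cycle 10, and the block and leaving out the 3 Nissle samples of contradictory label in the list tests, were chosen after seeing the data. Of the counts of called assays, 194 stayed within 1.5 times the value reported and 40 did not. The 194 include counts that stayed at 0 for CEC against DNBS, Nissle against DNBS and CEC against Nissle, which say little about stability. Among the named assays 5955 values kept their direction and their side of the threshold, 41 passed where they had not, 31 no longer passed and 116 changed sign. Atrn alone was called in the main fits, so every other named assay that kept its side did so by staying uncalled. Of the called lists, 209 values stayed called and 81 did not, with none in the opposite direction. Detection counts were 0 under all settings as well, which says nothing about stability, since Fisher's exact test needs at least 15 full separations here and 1 to 3 assays per comparison had an unadjusted p under 0.05. Values that changed are given next, and the cause was not tested unless it is named. With limma's median SE of 0.42 and 42% of simulated changes of log2 1 recovered between the DNBS and healthy groups, changes of about that size could go undetected. Larger ones could too where the spread over all 4 groups, which share 1 estimate, is wide. The differences of Il6_Mm00446190_m1 and Cxcl2 between the DNBS and healthy groups were not called in the main fit. They passed in the limma fit to these groups alone (adjusted p = 0.000468 and 0.00332) and without Nissle 1 (0.0119 for each). Of all cells 9.82% had no value, and the 26 assays without any value, such as Tnf and Il10, could not be compared.

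Atrn kept its direction in every setting run, and it was called between the DNBS and healthy groups in all but the fit without normalization (log2 -2.81, adjusted p = 0.109), where 0 assays were called in the DNBS, CEC and Nissle groups against healthy (63, 8 and 42 at an unadjusted p under 0.05). In the CEC group (adjusted p from 7.64e-07 to 0.990 over the settings) limma called 0 assays also with the median (Atrn adjusted p = 0.0563), quantile normalization (0.133), values past cycle 28 missing (0.0556), no trend in the variance (0.0745), a fit to both groups alone (0.201) and without the 3 Nissle samples of contradictory label (0.0652). In the Nissle group (1.27e-07 to 0.501) the count was 0 in the fit to both groups alone (0.0911) and without those 3 samples (0.0849), which leaves 2 Nissle samples. Missing values set to the highest Ct plus 1 gave 2 calls each for CEC and Nissle against healthy, the added one being Scgb3a1 (log2 10.7 and 9.82), an assay without a value in any healthy sample. The fit to both groups alone called 9 assays for DNBS against healthy, 6 higher and 3 lower, centring sections 3 (1 higher, 2 lower), and array weights 101 (49 higher, 52 lower, 22 of them single-exon), as well as 47 for CEC against DNBS (25 higher, 22 lower). Array weights were lowest for Nissle 1 (0.252), healthy 5 (0.262) and DNBS 5 (0.391). Leaving out 1 sample gave 1 to 7 called assays for DNBS against healthy, 0 to 1 for CEC and 0 to 1 for Nissle against healthy.

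Without normalization the median over all assays moved by 0.23 for DNBS, 0.43 for Nissle against healthy, -0.19 for CEC and 0.21 for Nissle against DNBS, and -0.40 for CEC against Nissle. Reference assays moved it by 0.17 for Nissle against DNBS and -0.18 for CEC against Nissle, the median by 0.15 for CEC against DNBS, and quantile normalization by 0.11 for Nissle against healthy. Under each scaling the medians of the called lists kept their sign (1.74 to 2.09 for neutrophil markers in the DNBS against the healthy group).

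With an estimated correlation and with fry, 0 lists were called for DNBS, CEC and Nissle against healthy and for CEC against Nissle, where camera with the preset correlation called 1, 2, 4 and 3. Reference assays gave 2 called lists for DNBS against healthy (the added one pro-inflammatory cytokines, as in the next 2 settings), 1 for CEC against healthy and 1 for CEC against Nissle, and leaving out the 3 samples of widest shifts gave 2 and 1 for the first and second of these. Values under cycle 10 set to missing gave 2 for DNBS against healthy, centring sections 1 for CEC against DNBS, and the fit without single-exon assays 0 for CEC and 2 for Nissle against healthy. The adhesion and cytokine lists hold no single-exon assay and kept all their members in that fit, while the macrophage list holds the single-exon assay of Cx3cr1. Without the 3 Nissle samples of contradictory label 3 lists were called higher for Nissle against DNBS (adjusted p = 0.0308 for each), with 2 Nissle samples left. Leaving out 1 sample gave 0 to 2 called lists for DNBS, 0 to 4 for CEC and 0 to 5 for Nissle against healthy, 0 to 2 for CEC and 0 to 2 for Nissle against DNBS, and 0 to 4 for CEC against Nissle. Over the samples left out, the adjusted p of the neutrophil list for DNBS against healthy ranged from 0.0046 to 0.133, and for CEC against healthy that of the macrophage list from 0.0025 to 0.170 and that of the adhesion list from 0.0205 to 0.227.

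The covariance of the CEC and DNBS changes was -0.27 after centring sections (permutation p = 0.0323) and -0.48 without the 3 samples of widest shifts (permutation p = 0.0238), and -0.41 to -0.12 over the samples left out. For Nissle it was 0.26 without the 3 samples of contradictory label (permutation p = 0.174), which leaves 2 Nissle samples, and -0.27 to 0.034 over the samples left out, above 0 without DNBS 4 (0.034) and Nissle 5 (0.023). For CEC with Nissle it was -0.033 without those 3 samples (permutation p = 0.844).

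With the sample number as a block, limma called 2 assays for DNBS against healthy (1 higher, 1 lower), and 0 for CEC (Atrn log2 -2.01, adjusted p = 0.777) and for Nissle against healthy (Atrn log2 -2.69, adjusted p = 0.152). Lists called with the block numbered 0 for DNBS, 1 for CEC and 0 for Nissle against healthy, 1 for CEC against DNBS (chemokine and chemoattractant receptors, adjusted p = 0.0498) and 0 for CEC against Nissle, and the block changed no other call. Several of these receptors have single-exon assays, whose median was 0.64 for CEC against DNBS. With an estimated correlation and no block, no list passed in that comparison (camera, smallest adjusted p = 0.705). As for the DNBS and healthy groups, a pairing of samples by number is not established for the other groups. The deviations of same-numbered samples correlated at 0.11 to 0.13 for the 2 numbers shared by CEC and healthy, -0.40 to -0.15 for Nissle and healthy, -0.12 to 0.34 for CEC and DNBS, -0.27 to 0.35 for Nissle and DNBS, and -0.35 to 0.44 for CEC and Nissle. Of the shared numbers, 2 of 2 correlated best with themselves for CEC and healthy, too few pairs to decide, 0 of 3 for Nissle and healthy, 1 of 3 for CEC and DNBS, 1 of 5 for Nissle and DNBS, and 2 of 3 for CEC and Nissle. Signs reversed with the block for Il12b_Mm99999067_m1 (-1.11) for DNBS against healthy, Il12b_Mm99999067_m1 (-0.61) and Ptgs2_Mm00478374_m1 (-0.74) for CEC against healthy, Itgam_Mm00434455_m1 (-0.62), Il12b_Mm99999067_m1 (-0.26), Il12b_Mm00434174_m1 (-0.51) and Ptgs2_Mm00478374_m1 (-0.019) for Nissle against healthy, Nos2_Mm00440502_m1 (0.28), Ifng_Mm99999071_m1 (0.38) and Il12b_Mm00434174_m1 (-0.24) for CEC against DNBS, Ifng_Mm99999071_m1 (0.36) for CEC against Nissle.

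Array weights reversed the log2 changes of Il12b_Mm99999067_m1 (-0.27) and Il6_Mm01210733_m1 (1.93) for DNBS against healthy, Il1b_Mm99999061_mH (0.043), Ifng_Mm99999071_m1 (-0.27) and Il12b_Mm00434174_m1 (0.14) for CEC against healthy, Itgam_Mm00434455_m1 (-0.26), Nos2_Mm00440502_m1 (-0.064) and Ptgs2_Mm00478374_m1 (-0.041) for Nissle against healthy, Nos2_Mm00440502_m1 (0.13) for CEC against DNBS, Il1b_Mm01336189_m1 (-0.97) and Ifng_Mm99999071_m1 (-0.061) for Nissle against DNBS, Il12b_Mm99999067_m1 (0.79), Il12b_Mm00434174_m1 (0.13) and Ptgs2_Mm00478374_m1 (0.36) for CEC against Nissle. Centring sections reversed Il1b_Mm99999061_mH (0.024) and Ifng_Mm99999071_m1 (-0.24) for CEC against healthy, Itgam_Mm00434455_m1 (-0.26) for Nissle against healthy, Il12b_Mm99999067_m1 (-0.10) for CEC against DNBS, Mapk8_Mm00489514_m1 (-0.30), Il1b_Mm01336189_m1 (-0.34) and Ifng_Mm99999071_m1 (-0.25) for Nissle against DNBS, Ifng_Mm01168134_m1 (-0.17) for CEC against Nissle. Without the 3 samples of widest shifts, the sign turned for Il1b_Mm99999061_mH (0.12), Ifng_Mm99999071_m1 (-0.19) and Il12b_Mm00434174_m1 (0.031) for CEC against healthy, Mapk8_Mm00489514_m1 (-0.10), Il1b_Mm01336189_m1 (-0.67) and Ifng_Mm99999071_m1 (-0.42) for Nissle against DNBS. Leaving out the 3 Nissle samples of contradictory label reversed Nos2_Mm00440502_m1 (0.15), Il6_Mm01210733_m1 (0.74), Il1b_Mm99999061_mH (1.28), Il6_Mm00446190_m1 (0.63) and Ptgs2_Mm00478374_m1 (0.34) for Nissle against DNBS, Nos2_Mm00440502_m1 (-0.22) and Ifng_Mm01168134_m1 (-0.71) for CEC against Nissle. Missing values set to the highest Ct plus 1 reversed Il6_Mm01210733_m1 (3.16) for DNBS against healthy, Il6_Mm01210733_m1 (0.22) for CEC against healthy, Il6_Mm01210733_m1 (0.83) for Nissle against healthy. No normalization reversed Nos2_Mm00440502_m1 (0.017) for Nissle against DNBS, Nos2_Mm00440502_m1 (-0.27) and Ifng_Mm01168134_m1 (-0.39) for CEC against Nissle. Reference assays reversed Nos2_Mm00440502_m1 (-0.054) and Ifng_Mm01168134_m1 (-0.17) for CEC against Nissle. Values past cycle 28 set to missing reversed Ifng_Mm01168134_m1 (-0.58) for CEC against DNBS, Ifng_Mm01168134_m1 (-0.53) for Nissle against DNBS, Ifng_Mm01168134_m1 (-0.051) for CEC against Nissle. A limit at cycle 32 reversed Ifng_Mm01168134_m1 (-0.0028) for CEC against Nissle. Scaling to the median reversed Nos2_Mm00440502_m1 (0.079) for CEC against DNBS. Quantile normalization reversed Ifng_Mm99999071_m1 (-0.13) for Nissle against DNBS.

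Leaving out samples 1 at a time turned the sign of these log2 changes, given with their range: Il12b_Mm99999067_m1 at -0.19 to 0.70 (DNBS against healthy) and -0.50 to 0.27 (CEC against Nissle), Il17a_Mm00439618_m1 at -0.47 to 0.15 (CEC against healthy), Il1b_Mm99999061_mH at -0.60 to 0.17 (CEC against healthy), Ifng_Mm99999071_m1 at -0.22 to 0.57 (CEC against healthy) and -0.31 to 0.43 (Nissle against DNBS). The same held for Il12b_Mm00434174_m1 at -0.76 to 0.43 (CEC against healthy), -0.40 to 0.95 (Nissle against healthy), -0.11 to 0.89 (CEC against DNBS) and -1.11 to 0.23 (CEC against Nissle), Ptgs2_Mm00478374_m1 at -0.12 to 0.49 (CEC against healthy), -0.11 to 0.65 (Nissle against healthy) and -0.49 to 0.28 (CEC against Nissle), Itgam_Mm00434455_m1 at -0.14 to 0.36 (Nissle against healthy), Nos2_Mm00440502_m1 at -0.36 to 0.15 (CEC against DNBS), -0.49 to 0.0073 (Nissle against DNBS) and -0.075 to 0.34 (CEC against Nissle). Sign changes also occurred for Il1b_Mm01336189_m1 at -1.09 to 0.67 (Nissle against DNBS) and -1.33 to 0.33 (CEC against Nissle), Il6_Mm01210733_m1 at -1.38 to 0.91 (CEC against Nissle), Il6_Mm00446190_m1 at -1.93 to 0.13 (CEC against Nissle), Ifng_Mm01168134_m1 at -0.21 to 0.43 (CEC against Nissle).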

Other observations

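The counts after centring sections and those by shared sample number were chosen only after the results were seen. Whether DNBS-treated mucosa differed in the sensing and execution of cell death was read from a list of 8 inflammasome and cell death genes, which was not called in any comparison. Against the healthy controls 6 of 8 members were lower in the DNBS group (median log2 -0.42, camera adjusted p = 0.417; 0.848 with an estimated correlation), 7 of 8 in the CEC group (-0.51, adjusted p = 0.171; 0.544) and 5 of 8 in the Nissle group (-0.46, adjusted p = 0.323; 0.728), and these medians stayed below 0 under each scaling. The same 5 healthy samples enter all 3 comparisons. Casp1, the inflammasome protease gene named after its values were seen, differed by -0.54 (SE 0.26), -0.48 and -0.63 in the DNBS, CEC and Nissle groups, and the death receptor gene Fas, named in the same way, by -0.73 (SE 0.48), -1.08 and -0.78. Neither passed over all assays (limma, adjusted p from 0.331 to 0.803). Without CEC 5 the list was called lower in the CEC group (adjusted p = 0.0421).

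Interferon response and STAT signalling genes, 20 in all, were not called either. Against the healthy controls 15 of 20 were lower in the DNBS group (median log2 -0.18, camera adjusted p = 0.417; 0.848 with an estimated correlation), 14 in the CEC group (-0.25, adjusted p = 0.235; 0.701) and 13 in the Nissle group (-0.24, adjusted p = 0.445; 0.817), and without normalization the medians of the DNBS (0.053) and Nissle groups (0.20) lay above 0. Without CEC 5 this list was called lower in the CEC group (adjusted p = 0.0483). Between the DNBS-treated groups neither list came near the threshold (adjusted p from 0.896 to 0.993). Of its members, named after their values were seen, the interferon transcription factor gene Irf3 (assay Irf3_Mm00516779_m1) differed from the healthy controls by -0.83 (SE 0.37) in the CEC and -0.86 in the Nissle group and by -0.032 in the DNBS group, and the interferon gamma receptor gene Ifngr2 by -0.65 (SE 0.30), -0.27 and -0.66 in the DNBS, CEC and Nissle groups. Ifnb1, measured with a single-exon assay, differed by -1.93 (SE 0.59) in the DNBS group. None of these passed (limma, adjusted p from 0.122 to 0.979).

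The Nissle samples of contradictory label had relative Atrn levels (assay Atrn_Mm00437746_m1) of 0.039 (Nissle 3), -0.62 (Nissle 4) and 1.07 (Nissle 5), and the lowest healthy sample stood at 1.39. Their means over the neutrophil markers (-0.50, -0.29 and -0.99) lay within the healthy range of -1.68 to -0.25. So did those of DNBS 5 (-0.96), CEC 5 (-1.15), CEC 7 (-1.55) and CEC 8 (-0.83). These values do not settle which label is right.

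Each count of calls was set against 100 random splits of the same 10 samples, the real one included. A split counts calls of any assay, so these counts do not test the separation in Atrn itself and do not rank the Atrn calls of the groups. For the DNBS against the healthy group chance could not be excluded for the count of 1 called assay (9 splits gave as many, highest other 15) or the 1 called list (31 splits, highest other 3), nor for the 83 assays with an unadjusted p under 0.05 (11 splits, highest other 139). The splits with up to 15 calls, many times the real count, point to a structure of the samples. Same-numbered samples of these groups deviated together, which 3 pairs do not establish as a pairing. These deviations include section shifts, which healthy 5 and DNBS 5 shared (1.97 and 1.18 cycles in section 1). The other pairs differed in sign there (-0.69 and 0.29 for number 3, -0.50 and 0.059 for number 4). How far shared shifts account for the correlations was not tested. The 15 splits that part all 3 pairs, as the real one does, gave no call of an assay but the real one (highest other 0), while the 85 that keep a pair together gave as many in 8 cases. These 15 are too few for a share under 0.05. For lists, 6 of those 15 splits gave as many (highest other 2). After centring sections the 3 called assays were reached by no other split (1 of 100, highest other 0), and with array weights the 101 calls by none either (highest other 67).

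For the CEC and Nissle groups against healthy, 2 of 100 splits in each comparison, the real one included, gave as many as the count of 1 assay (highest other 1 and 10). This share lies under 0.05, but it was not adjusted over the comparisons and does not exclude chance. For Nissle both lay among the 17 splits that part all 3 shared numbers, too few for a share under 0.05. The CEC call was lost in 14 of 20 fits that left out 1 sample. Chance could not be excluded for the 2 and 4 called lists (35 splits, highest other 6, and 22 splits, highest other 8). For CEC against Nissle it could not be excluded for the 3 called lists (50 splits, highest other 7). With 0 assays called by limma for CEC against DNBS, Nissle against DNBS and CEC against Nissle (61, 24 and 8 at an unadjusted p under 0.05), all 100 splits gave as many by construction, which says nothing about chance, and the highest others were 11, 34 and 29. With 0 lists called for CEC and Nissle against DNBS, the 100 splits say nothing about chance either (highest other 6 in both). Such splits, with up to 34 calls, point to a structure of the samples here too, and for the 47 assays called with array weights for CEC against DNBS chance could not be excluded (12 splits, highest other 100).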
